A study of Caenorhabditis elegans with 4 samples.

How the data were processed

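Poly(A) RNA of C. elegans N2 hermaphrodites fed OP50 or MI-OMU01 was sequenced in 4 libraries, 2 per group. Per the labels' protocols, total RNA was extracted from worms kept in RNAlater, messenger RNA was enriched with magnetic beads, and libraries were made with a stranded kit and read on an Illumina HiSeq. The deposited files hold whole-number counts of reads per gene, not normalized, with 1 file per library. Per the submitters' processing notes the tools were Trim Galore 0.6.5, Trimmomatic 0.39, cutadapt 2.7, STAR 2.7.2b and featureCounts 1.6.4, and the builds were ce11 and WBcel235. The order and settings of these tools, the annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping genes and of antisense partners may therefore be mixed, and reads of near-identical copies (vitellogenins, hsp-16 pairs, collagens, abu, F-box and MATH, histone and major sperm protein genes) may be split or lost, so values of these genes are uncertain.

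The tables list 46881 genes by WormBase identifier, and 22417 had a read in at least 1 library. Symbols came from the files, and gene types and coordinates from the Ensembl release 115 annotation of WBcel235, which matched 46794 of the genes. The gene written T24B8.5 is also called sysm-1. No line of the tables named something other than a gene. Groups came from the sample titles. Within a group the chi-square per gene of the counts was 11.3 (OP50) and 9.91 (MI-OMU01), above sampling noise, as can also arise between preparations of 1 RNA. The libraries were treated as separate samples because their titles number them as replicates. Totals ran from 16962082 to 24381952 reads. A count of 3, taken as the limit that a count of 0 allows, is 0.177 and 0.173 counts per 1e6 reads of the raw totals in the OP50 libraries and 0.170 and 0.123 in the MI-OMU01 libraries, before TMM scaling. Reads carry no molecular identifiers, so intervals (95%, exact binomial for ratios of reads) and floors cover counting error only.

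The main test was edgeR 4.0.16 (R 4.3.3): genes were kept with filterByExpr (minimum count 10, minimum total 15), libraries were scaled with TMM (factors 0.962, 0.948, 1.05 and 1.04), and a robust quasi-likelihood model with the group as its only term was fitted, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.0965. CPM values are TMM-scaled. SE of a log2 fold change is its size over the square root of the F statistic. The test, the lists, the naming rule and the alternatives listed first below were chosen before the data were examined. Named were the 12 largest rises and 12 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM and groups that do not overlap, up to 3 risen and 3 fallen genes per list, and 18 genes fixed in advance (acdh-1, sod-3, mtl-1, hsp-16.2, gst-4, fat-7, fat-5, acs-2, vit-2, vit-5, lys-7, irg-4, irg-5, T24B8.5, fmo-2, pmk-1, daf-16 and skn-1). The rule named 224 genes, of which 221 passed the threshold, and not each is printed. The lysozyme gene lys-7 was among those that did not (log2 fold change 0.25, adjusted p = 0.0906; 0.0417 without OP50 replicate 1, 0.00989 with total counts as library sizes and 0.0491 with the filter at 5 CPM).

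The 46 gene lists were written from general knowledge of C. elegans, none of them chosen on these samples, and 2 of their names (F49F6.5 and mua-1) had no match. Some genes are in more than 1 list. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 46 lists, then with an estimated correlation and with fry. With an estimated correlation camera takes its p-value from the residual degrees of freedom, which are few in this design. It could then hardly pass any list, so those adjusted p-values do not show by themselves that correlation between genes undid a call.

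Alternatives were DESeq2 1.42.0 size factors or total counts in edgeR, DESeq2, limma-voom, no filter on low counts, a filter of 5 CPM in 2 libraries, each library left out, the replicate number as a block, removal of the trend with gene length, protein-coding genes only, the 10 most abundant genes left out, and a test against a fold of 1.5 (glmTreat). Thinning to 1 total and summing of near-identical copies were added later. A correction for GC content was not run, because no genome sequence was used here. On simulated counts 200 genes among 14687 were changed, and a further list of 30 genes was shifted. For the 200 genes edgeR recovered 47.1% of 1.5-fold, 78.6% of 2-fold and 96.7% of 4-fold changes, with 6 false calls. With no gene changed it made 3 calls among 14708 genes. Far fewer genes changed there than were called in the data, and libraries were drawn as independent, so these rates may be too favourable.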

Results

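The series profiled messenger RNA of Caenorhabditis elegans hermaphrodites of the wild-type Bristol N2 strain on different bacterial lawns. One group was fed Escherichia coli OP50, the standard laboratory food, and the other was fed MI-OMU01, a natto strain of Bacillus subtilis. Worms were 3 days old when moved to the lawns and stayed there for 1 day, and about 200 worms were collected per group. Each group held 2 libraries. The OP50 libraries held 16962082 and 17327035 counted reads, and the MI-OMU01 libraries held 17601286 and 24381952. Between 18952 and 20516 genes had at least 1 read in a library. Within a group the libraries correlated across genes at Pearson's r of 0.996 (OP50) and 0.997 (MI-OMU01) on log2(CPM + 1), and between groups at 0.977 to 0.979. Genes are not independent replicates, so these values describe likeness only. No label says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

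The comparison asked which genes were regulated by feeding on the B. subtilis strain. Worms fed MI-OMU01 held far more transcript of several lysozymes, enzymes that break bacterial cell walls, and far less transcript of many cuticle collagens. The invertebrate-type lysozyme gene ilys-2 stood at 637 ± 72.1 CPM (SD, n = 2) in MI-OMU01-fed worms and at 0.918 ± 0.437 CPM in OP50-fed worms, a fold of 690 (adjusted p = 1.34e-16). The collagen gene col-161 stood at 1.36 ± 0.240 CPM against 133 ± 21.2 CPM in OP50-fed worms, 95.7-fold lower (adjusted p = 3.77e-15). The vitellogenin gene vit-4, 1 of 6 yolk protein genes, fell 32.8-fold (log2 fold change -5.04, and -4.03 with reads of its near-identical copy vit-3 added), and the acyl-CoA dehydrogenase gene acdh-1 of the propionate shunt fell 5.39-fold. The lysosomal lipase genes lipl-1 and lipl-3 rose by 4.59 and 4.52 on the log2 scale.

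In edgeR's quasi-likelihood test 4449 of 14967 genes passed an adjusted p of 0.05, 2178 higher and 2271 lower in MI-OMU01-fed worms. At least a 2-fold change was seen in 965 of the higher and 949 of the lower genes. Both MI-OMU01 libraries lay on the same side of both OP50 libraries for 63.1% of the genes, where chance gives 33.3%. Without MI-OMU01 replicate 2, 2935 genes passed (1262 higher), and without MI-OMU01 replicate 1, 1505 genes were lower. With total counts as library sizes 3206 genes were higher and 1706 lower, so that 65.3% of the calls were higher against 2178 of 4449 with TMM scaling. That scaling moved the median log2 fold change of all tested genes from 0.03 to 0.16, and folds here are relative to the TMM scale.

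**Figure D1:**
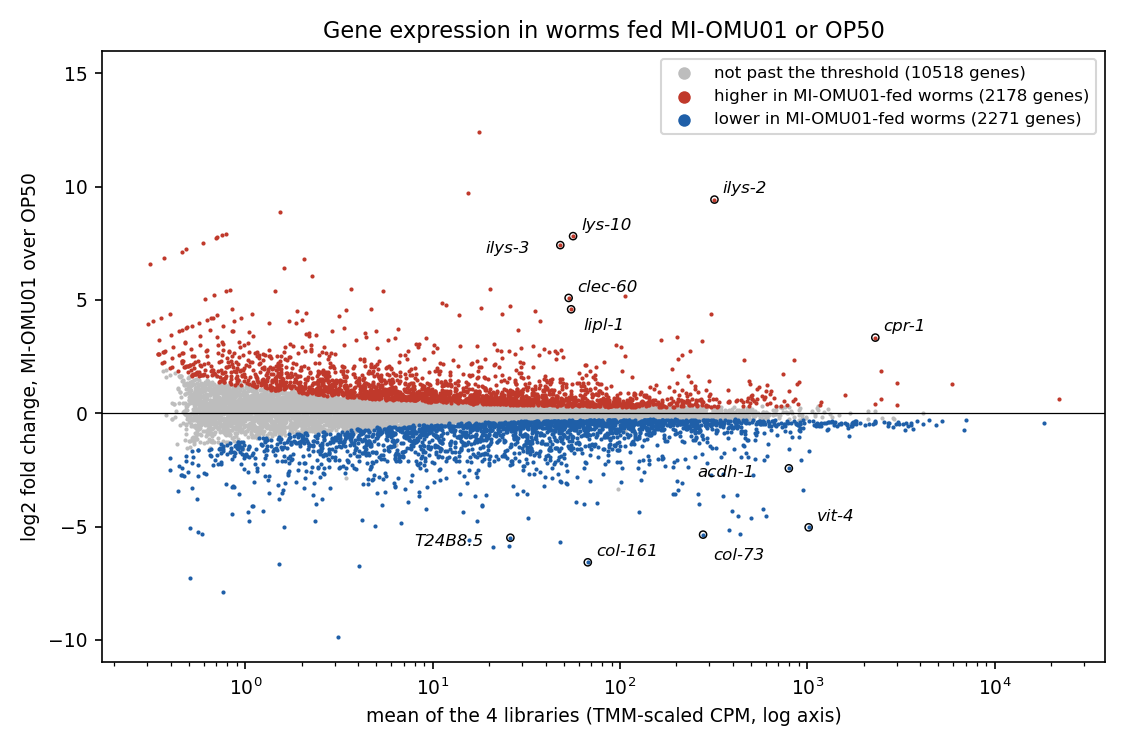
Log2 fold change (MI-OMU01 over OP50) of the 14967 tested genes against the mean TMM-scaled CPM of the 4 libraries on a log axis, each point a gene, red for the 2178 higher, blue for the 2271 lower and grey for the rest. The circled lysozyme gene ilys-2 lies at 9.43 and the collagen gene col-161 at -6.58.

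Among the 12 largest rises, Y53G8AM.5 (WBGene00021805, chromosome III, 3256730 to 3258395 in WBcel235) had no read in the OP50 libraries and 1554 reads in the MI-OMU01 libraries. It was at least 386-fold higher against a floor of 3 counts over the OP50 group. The C-type lectin gene clec-9 had 1 read in the OP50 libraries and 1376 in the MI-OMU01 libraries, and the counting interval of this ratio starts at 184. Next came ilys-2 (WBGene00016669, chromosome IV, 2467681 to 2468810), lys-10 (226-fold, log2 fold change 7.82, SE 0.20) and ilys-3 (171-fold, log2 fold change 7.42, SE 0.20), the last lying beside ilys-2. The acyltransferase-like gene oac-20 rose 44.5-fold, the lectin gene clec-60 by 5.09 on the log2 scale and the UDP-glycosyltransferase gene ugt-18 by 4.74. Among the 12 largest falls, 5 were collagen genes: col-161 (WBGene00000734, chromosome V, 13317028 to 13318011), col-162 (57.4-fold lower), col-73 (log2 fold change -5.36), col-101 (39.8-fold) and col-90 (35.3-fold). The adjusted p of col-101 was 0.203 without OP50 replicate 1 and 0.195 without OP50 replicate 2, when its spread came from the MI-OMU01 pair alone, while its log2 fold change stayed at -5.25 and -5.42. The uncharacterized gene K02E11.10 fell 51.6-fold, abu-15 48.1-fold and T24B8.5, a target of the p38 pathway, 45.1-fold. For abu-15 the log2 fold change ran from -6.53 to -5.14 over the alternatives.

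**Figure D2:**
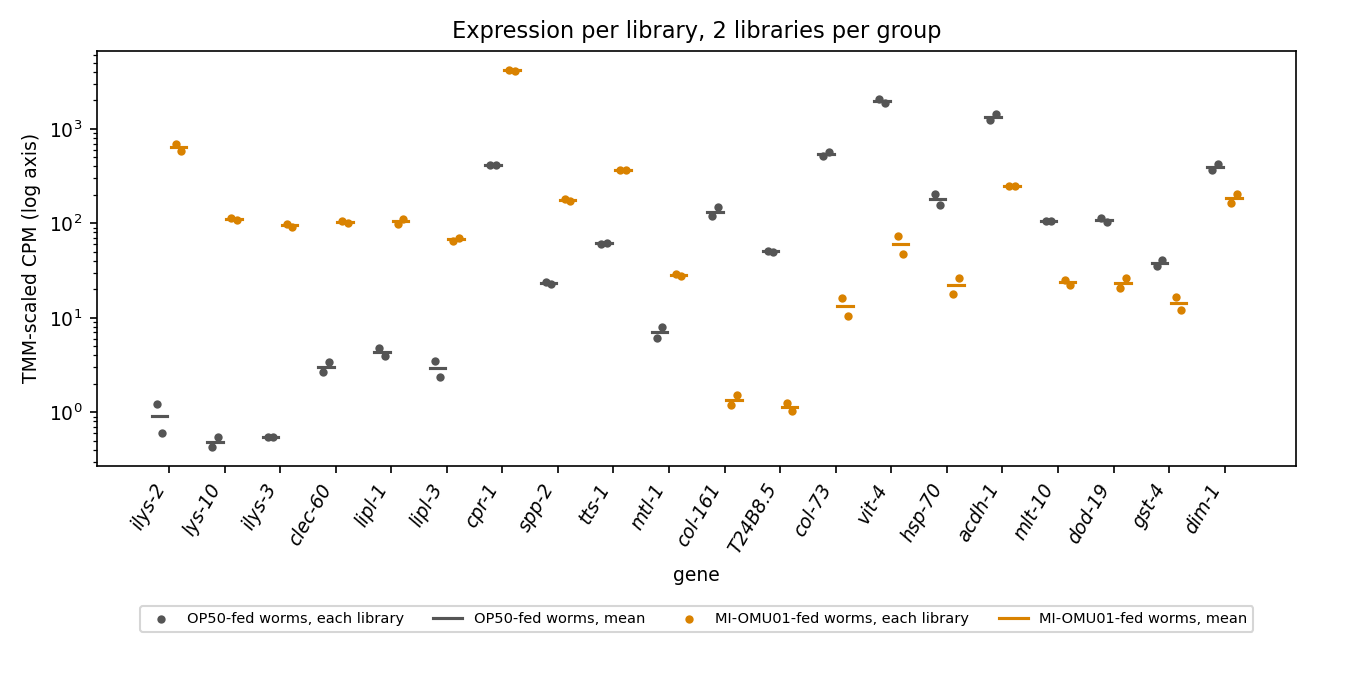
TMM-scaled CPM on a log axis of 20 genes in each library, with OP50-fed worms in grey and MI-OMU01-fed worms in orange, points for the 2 libraries of a group and bars for their mean. The groups are apart for each gene plotted, with lys-10 at 0.489 and 112 CPM and T24B8.5 at 50.8 and 1.13 CPM in OP50-fed and MI-OMU01-fed worms.

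Genes for defence against bacteria moved both ways. Of 9 tested genes known to respond to Staphylococcus aureus, 8 rose and none fell, with a median log2 fold change of 4.55 (camera adjusted p = 1.82e-35; adjusted p = 0.261 with an estimated correlation). They included ilys-2, ilys-3 and the cathepsin B-like protease gene cpr-2, which rose from 0.152 ± 0.129 to 7.13 ± 1.03 CPM (SD, n = 2). Of 13 lysozymes, 7 rose and 2 fell, lys-2 by 3.19-fold and lys-1 by 1.63-fold (camera adjusted p = 8.45e-22; adjusted p = 0.301 with an estimated correlation). The saposin-like genes, which code for membrane-permeabilizing peptides, had 10 higher and 3 lower of 16 (camera adjusted p = 0.000201; adjusted p = 0.301 with an estimated correlation). Here spp-2 rose 7.69-fold and spp-8 5.20-fold, while spp-17 fell 4.66-fold and spp-13 3.77-fold. The pals genes of the intracellular pathogen response had 15 higher and none lower of 26, with pals-32 up 12.4-fold (camera adjusted p = 8.27e-06; adjusted p = 0.301 with an estimated correlation). For pals-32 the log2 fold change ran from 3.10 to 4.40 over the alternatives. Adjusted over the list alone, the genes past the threshold numbered 8, 11, 14 and 16 in these lists.

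The infection response effectors, by contrast, had 8 lower and 4 higher of 13 (camera adjusted p = 3.39e-05, direction down; adjusted p = 0.309 with an estimated correlation). T24B8.5 fell from 50.8 ± 0.868 to 1.13 ± 0.159 CPM (SD, n = 2), C17H12.8 fell 5.27-fold and K08D8.5 4.33-fold, while irg-1 rose 3.16-fold. The rise of irg-4 (1.67-fold) had an adjusted p of 0.234 without MI-OMU01 replicate 2, which left 2 higher effectors. The fall of irg-5 (4.05-fold) had an adjusted p of 0.0759 without OP50 replicate 1 and 0.115 without MI-OMU01 replicate 1. C-type lectins had 39 higher and 25 lower of 125 (camera adjusted p = 0.142), with clec-70 up 19.4-fold and clec-42 down 5.36-fold. Antimicrobial peptide genes had 12 higher and 8 lower of 38 (camera adjusted p = 0.775), and the 8 lower were 4 without MI-OMU01 replicate 1. F-box and MATH genes, many of them substrate adaptors of ubiquitin ligases, had 59 higher and 4 lower of 310 (camera adjusted p = 0.00345; adjusted p = 0.309 with an estimated correlation). All protein-coding genes at up to 1 CPM and at 1 to 5 CPM had median log2 fold changes of 0.32 and 0.19, near the median of 0.28 of the F-box and MATH genes. Their higher genes numbered 39 without MI-OMU01 replicate 2, and their lower genes 9 without OP50 replicate 2. In these 4 lists 12, 68, 23 and 59 genes passed when adjusted over the list alone.

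Genes induced by the FOXO transcription factor DAF-16, which acts downstream of insulin signalling, had 11 higher and none lower of 14 (camera adjusted p = 7.96e-10; adjusted p = 0.301 with an estimated correlation). The long non-coding RNA tts-1 rose 5.99-fold, from 61.6 ± 0.632 to 369 ± 1.63 CPM (SD, n = 2). The metallothionein gene mtl-1 rose 4.06-fold, the ferritin gene ftn-1 4.08-fold and the superoxide dismutase gene sod-3 2.44-fold. Of 8 DAF-16 repressed genes, 6 fell and 2 rose (camera adjusted p = 0.0142, direction down; adjusted p = 0.335 with an estimated correlation). Here dod-19 fell 4.64-fold and dod-17 4.29-fold, while dod-21 rose 6.55-fold and the insulin-like peptide gene ins-7 4.55-fold. The transcript of daf-16 itself rose 1.31-fold (adjusted p = 0.0119), with an adjusted p of 0.0556 without OP50 replicate 2 and 0.202 without MI-OMU01 replicate 2. Of 18 p38 and insulin signalling components 4 were higher and none lower (camera adjusted p = 0.221), 2 of them higher without OP50 replicate 1 and 1 without MI-OMU01 replicate 2, and 1 was lower without either OP50 library; with total counts as library sizes 8 were higher. The kinase gene pmk-1 had a log2 fold change of 0.18 (adjusted p = 0.340). Of 24 insulin-like peptide genes 9 were higher and 4 lower, 2 lower without OP50 replicate 2, and the camera adjusted p of 0.0829 was 0.0430 without that library. The neuronal peptide gene daf-28 fell 2.71-fold. Adjusted over the list alone, 11, 8, 2 and 13 genes passed.

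Chaperone genes were mostly lower. Of 20 heat shock genes 15 fell and 3 rose (camera adjusted p = 1.12e-06, direction down; adjusted p = 0.391 with an estimated correlation). The stress-inducible hsp-70 fell from 180 ± 36.2 to 22.1 ± 6.04 CPM (SD, n = 2), an 8.12-fold change (adjusted p = 1.97e-07), and hsp-12.6 rose 4.29-fold. The fall of hsp-16.2 was of like size at 8.03-fold but its adjusted p of 0.0453 became 0.358 without OP50 replicate 1 and 0.322 without OP50 replicate 2, with log2 fold changes of -2.84 and -3.19. It was 0.0589 with total counts as library sizes, 0.137 with no filter on low counts and 0.0600 with the gene length trend removed, at like folds. In the mitochondrial unfolded protein response 5 of 11 genes fell, among them hsp-60 by 3.53-fold and hsp-6 by 1.78-fold (camera adjusted p = 0.0272; adjusted p = 0.363 with an estimated correlation). In the endoplasmic reticulum response 9 of 18 genes fell and 1 rose, with hsp-4 down 1.74-fold and pdi-6 down 1.69-fold (camera adjusted p = 0.0457; adjusted p = 0.487 with an estimated correlation). Without either MI-OMU01 library 5 endoplasmic reticulum genes and 3 mitochondrial response genes were lower, and a rise in the former remained in 0 genes without OP50 replicate 1 or either MI-OMU01 library. The endoplasmic reticulum call ended without MI-OMU01 replicate 1 (adjusted p = 0.0969) and replicate 2 (0.0563), and the mitochondrial call without MI-OMU01 replicate 2 (0.0837). With total counts as library sizes their adjusted p-values were 0.116 and 0.0524, with 5 and 2 genes lower and 2 and 1 higher. Without OP50 replicate 2, 1 mitochondrial response gene was higher. In these lists 18, 5 and 11 genes passed when adjusted over the list alone.

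Antioxidant and SKN-1 target genes had 8 higher and 6 lower of 23 (camera adjusted p = 0.954). Their median (0.06) and mean (0.17) log2 fold changes were above 0 while the camera direction was down, and the median fell below 0 after removal of the gene length trend. The glutathione S-transferase genes gst-4 and gst-10 fell 2.68-fold and 3.19-fold, while sod-5 rose 6.62-fold. The log2 fold change of sod-5 ran from 1.81 to 3.27 over the alternatives. The transcription factor gene skn-1 had a log2 fold change of -0.01 (adjusted p = 0.949). Of 43 glutathione S-transferases 8 were higher and 10 lower (camera adjusted p = 0.357), with a median of 0.13 and a mean of 0.09 against a camera direction of down. In the hypoxia and hydrogen sulfide response 4 were higher and 2 lower of 11 (camera adjusted p = 0.775), with the flavin monooxygenase gene fmo-2 up 3.40-fold and the prolyl hydroxylase gene phy-2 down 2.56-fold. Cytochromes P450, which oxidize lipids and foreign compounds, had 30 higher and 4 lower of 63 (camera adjusted p = 2.69e-05; adjusted p = 0.301 with an estimated correlation), with cyp-13A7 up 8.66-fold and cyp-34A10 up 8.07-fold. UDP-glycosyltransferases had 14 higher and 20 lower of 59 (camera adjusted p = 0.196), with ugt-8 at a log2 fold change of -3.81 and ugt-66 at -3.49. Adjusted over the list alone, 16, 18, 6, 34 and 38 genes of these lists passed. Without MI-OMU01 replicate 2 the higher genes numbered 5 (antioxidant), 3 (glutathione S-transferase) and 2 (hypoxia). Without OP50 replicate 2, 5 glutathione S-transferases were higher, and without MI-OMU01 replicate 1, 1 hypoxia gene and 2 cytochromes P450 were lower.

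Of the 6 vitellogenins 5 fell and vit-2 rose 1.53-fold (camera adjusted p = 1.13e-10, direction down; adjusted p = 0.335 with an estimated correlation). The rise of vit-2 had an adjusted p of 0.0700 without MI-OMU01 replicate 1, which left 0 higher genes. All vitellogenins held 5.17% and 4.72% of the reads in the OP50 libraries and 5.72% and 4.30% in the MI-OMU01 libraries. The fall was 10.4-fold for vit-3, 4.07-fold for vit-1 and 1.70-fold for vit-5, and near-identical copies make the split between vit-3, vit-4 and vit-5 uncertain. Of 11 propionate breakdown genes 5 fell and none rose (camera adjusted p = 1.59e-05; adjusted p = 0.301 with an estimated correlation). The shunt genes acdh-1, ech-6 and hphd-1 fell 5.39-fold, 2.89-fold and 2.55-fold, and acdh-1 went from 1343 ± 145 to 249.0 ± 0.255 CPM (SD, n = 2). In the methionine and folate cycle 12 of 23 genes fell and 2 rose (camera adjusted p = 3.34e-05, direction down; adjusted p = 0.301 with an estimated correlation). The peroxisomal-type transporter gene pmp-5 fell 5.33-fold and the cystathionine lyase gene cth-1 3.44-fold, and of the phosphocholine synthesis genes pmt-1 rose 3.28-fold and pmt-2 fell 2.71-fold. Without OP50 replicate 2 or either MI-OMU01 library 1 methionine and folate gene was higher, and without OP50 replicate 2 so was 1 propionate gene, as with total counts as library sizes. The genes past the threshold numbered 6, 5 and 14 when adjusted over the list alone.

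Fat metabolism genes split. The lysosomal lipase genes lipl-1, lipl-3 and lipl-2 rose, lipl-2 by 5.74-fold, while lips-6 fell 9.35-fold and lips-7 4.89-fold. Of 20 lipases 6 were higher and 7 lower (camera adjusted p = 0.116). Of 24 genes of fatty acid synthesis, desaturation and elongation 10 were higher and 7 lower (camera adjusted p = 0.120), 4 lower without MI-OMU01 replicate 2. The desaturase gene fat-3 rose 3.12-fold and fat-5 2.11-fold, and the 2.11-fold rise of fat-7 had an adjusted p of 0.0633 without MI-OMU01 replicate 1. Of 42 fatty acid oxidation genes 10 were higher and 14 lower (camera adjusted p = 0.142), with ech-9 up 7.98-fold and acdh-2 at a log2 fold change of -3.60. Without MI-OMU01 replicate 1, 8 were lower, and without MI-OMU01 replicate 2, 9 were lower and 6 higher, and 8 were lower with total counts as library sizes. The 1.38-fold rise of acs-2 had an adjusted p of 0.561 without MI-OMU01 replicate 2. Median log2 fold changes of lipases (0.02) and fatty acid oxidation genes (-0.06) changed sign with another scaling. When adjusted over the list alone, 14, 17 and 25 genes passed.

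The intestinal and lysosomal proteases had 12 higher and 2 lower of 20 (camera adjusted p = 8.45e-10; adjusted p = 0.301 with an estimated correlation). The cathepsin B-like gene cpr-1 rose from 415 ± 3.60 to 4195 ± 67.2 CPM (SD, n = 2), and the aspartyl protease gene asp-8 rose 7.80-fold. The lower proteases numbered 4 without OP50 replicate 2 and 0 without MI-OMU01 replicate 2, and 1 with total counts as library sizes. Autophagy and lysosome genes had 10 higher and 5 lower of 45 (camera adjusted p = 0.569), with lgg-1 up 1.73-fold. Their median (-0.01) and mean (0.06) log2 fold changes differed in sign, the camera direction was up, and with total counts as library sizes the median was above 0 and 1 gene was lower. The lower autophagy genes numbered 10 without OP50 replicate 1, 3 without OP50 replicate 2, 0 without MI-OMU01 replicate 1 and 1 without MI-OMU01 replicate 2, and the higher ones 6 and 3 without the latter pair. In haem and iron handling 4 were higher and 1 lower of 11 (camera adjusted p = 0.142), with ftn-2 up 1.51-fold and hrg-7 down 1.59-fold. Its higher genes numbered 2 without OP50 replicate 1 or MI-OMU01 replicate 2, and its lower genes 2 without OP50 replicate 2. In these lists 17, 15 and 5 genes passed when adjusted over the list alone.

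Cuticle genes formed the largest group of falls. Of 131 collagens 100 fell and 7 rose, with a median log2 fold change of -1.68 (camera adjusted p = 8.85e-78; adjusted p = 0.295 with an estimated correlation). The gene col-73 went from 541 CPM to 13.3 ± 3.98 CPM (SD, n = 2), while col-135 rose 5.97-fold. Of 16 larval and moulting markers 13 fell and 1 rose (camera adjusted p = 6.12e-18; adjusted p = 0.309 with an estimated correlation). The cuticle collagen gene sqt-1 had a log2 fold change of -3.60 and the moulting gene mlt-10 fell 4.45-fold. Hypodermis markers had 7 lower and 1 higher of 13 (camera adjusted p = 0.000671; adjusted p = 0.480 with an estimated correlation), with bus-8 down 3.56-fold and wrt-2 3.37-fold. Without OP50 replicate 1 or MI-OMU01 replicate 2 no hypodermis gene was higher, and without OP50 replicate 2 or with total counts as library sizes, 4 were. No moulting marker was higher without either MI-OMU01 library. Some collagen genes, sqt-1 among them, are also in the moulting list, and some are in the hypodermis list, so these lists are not separate evidence. Collagen family members share sequence, so reads may be split between copies. For these lists the genes adjusted over the list alone numbered 111, 15 and 10.

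Markers of other tissues moved in different directions. Body wall muscle markers had 17 lower and none higher of 21 (camera adjusted p = 3.38e-06; adjusted p = 0.487 with an estimated correlation), with dim-1 down 2.16-fold and the troponin I gene unc-27 2.13-fold, and 11 lower without MI-OMU01 replicate 1 and 1 higher without OP50 replicate 2. Pharynx markers had 13 lower and 6 higher of 24 (camera adjusted p = 2.56e-06, direction down; adjusted p = 0.487 with an estimated correlation). Of the 13 lower markers 10 were abu genes, all that were tested of that family (median log2 fold change -1.99). The lower count thus comes mainly from 1 family and does not show a fall of pharynx transcripts in general. The lower ones included abu-15 and abu-7 (31.7-fold), of a family of secreted proteins of the pharyngeal lining, while phat-3 rose 3.15-fold and marg-1 1.70-fold, and 2 were higher without OP50 replicate 1 or MI-OMU01 replicate 2. Neuron markers had 24 higher and none lower of 55 (camera adjusted p = 0.000656; adjusted p = 0.701 with an estimated correlation), with flp-10 up 2.18-fold. Of these 24 markers 19 were flp neuropeptide genes, of which 30 were tested. The count of higher neuron markers thus comes mainly from 1 family and does not by itself show a rise across neuron markers. Without OP50 replicate 1, 15 were higher and 3 lower and the camera adjusted p was 0.0661, and 13 were higher without MI-OMU01 replicate 2. Intestine markers had 5 higher and 6 lower of 19 (camera adjusted p = 0.569), with mtl-2 up from 19.7 ± 1.01 to 39.5 ± 6.45 CPM (SD, n = 2) and the peptide transporter gene pept-1 down 2.63-fold, and 3 were higher without OP50 replicate 1 or either MI-OMU01 library and 3 lower without MI-OMU01 replicate 1. Adjusted over the list alone, 18, 22, 26 and 13 genes passed.

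Germline markers gave few calls. Oocyte and germline markers had 1 higher and 2 lower of 33, with a median log2 fold change of -0.01 that was above 0 with total counts as library sizes (camera adjusted p = 0.970). TMM scaling centres on the bulk of genes, so neither this median nor the few calls can show whether the germline share of RNA changed. Of the called genes egg-5 fell 1.42-fold. When 1 library was left out, 0 to 4 were higher (4 without OP50 replicate 1) and 1 to 7 lower (7 without OP50 replicate 2), and with total counts as library sizes 1 was lower. Sperm markers had 2 higher and none lower of 44 (camera adjusted p = 0.192), namely gsp-3 and spe-41, with 0 higher without MI-OMU01 replicate 2 and 1 without OP50 replicate 2 or MI-OMU01 replicate 1, and 5 with total counts as library sizes. Early embryo markers had 1 higher and 6 lower of 16 (camera adjusted p = 0.403), with tbx-38 down 8.19-fold, and 2, 2 and 1 were lower without OP50 replicate 1, MI-OMU01 replicate 1 and MI-OMU01 replicate 2, where the first and second left 0 higher. With total counts as library sizes 3 were higher and 3 lower. The log2 fold change of tbx-38 ran from -5.43 to -1.99 over the alternatives. With values adjusted over the list alone, 1, 0 and 7 genes passed.

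Ribosomal protein genes fell by small folds. Of 80 cytosolic ribosomal protein genes 76 were lower and none higher, with a median log2 fold change of -0.46 (camera adjusted p = 1.47e-10; adjusted p = 0.487 with an estimated correlation). The gene rps-7 fell 1.51-fold, from 3444 ± 376 to 2285 ± 79.2 CPM (SD, n = 2). Of 33 proteasome genes 16 were lower and none higher (camera adjusted p = 0.00257; adjusted p = 0.701 with an estimated correlation). Nuclear genes of the mitochondrial respiratory chain had 10 lower and none higher of 48 (camera adjusted p = 0.0199; adjusted p = 0.526 with an estimated correlation), with ucr-2.2 down 1.52-fold, and their adjusted p was 0.0667 with total counts as library sizes. Mitochondrially encoded genes had 5 lower and none higher of 12, with ctc-2 down 1.73-fold (camera adjusted p = 0.0138; adjusted p = 0.530 with an estimated correlation). Glycolysis and tricarboxylic acid cycle genes had 2 higher and 10 lower of 40 (camera adjusted p = 0.142), with suca-1 down 1.46-fold. These counts varied with the scaling and the libraries used. Total counts as library sizes gave 4 (proteasome), 2 (respiratory chain), 3 (mitochondrially encoded) and 3 (glycolysis) lower genes, and 4 glycolysis genes and 1 ribosomal gene higher. Without MI-OMU01 replicate 1 the lower genes numbered 37 (ribosomal), 6 (proteasome), 2 (respiratory chain), 2 (mitochondrially encoded) and 3 (glycolysis), and without MI-OMU01 replicate 2 they numbered 48, 0, 3, 3 and 5. Without OP50 replicate 1, 21 respiratory chain genes and 10 mitochondrially encoded genes were lower and 1 ribosomal gene was higher, and without OP50 replicate 2, 27 proteasome genes were lower. The 2 higher glycolysis genes were 1 without OP50 replicate 2 or MI-OMU01 replicate 2 and 0 without MI-OMU01 replicate 1. Adjusted over the list alone, 76, 23, 10, 10 and 12 genes passed.

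Nuclear hormone receptors, ligand-gated transcription factors, had 61 higher and 14 lower of 200 (camera adjusted p = 0.00578; adjusted p = 0.701 with an estimated correlation). Their median log2 fold change of 0.34 was near that of all protein-coding genes at up to 1 CPM (0.32), so this call was not told apart from a general rise of weakly expressed genes. It did not end with the filter of 5 CPM in 2 libraries, which can keep a gene through its higher group alone. The gene nhr-208 rose 4.14-fold and nhr-17 fell 4.16-fold. Without MI-OMU01 replicate 2, 29 were higher, and the camera adjusted p was 0.121 without OP50 replicate 1. Histone genes had 6 higher and none lower of 24 (camera adjusted p = 0.184), 3 higher without either MI-OMU01 library and 1 lower without OP50 replicate 1, and 10 higher with total counts as library sizes. The counts adjusted over the list alone were 78 and 4. By annotated gene type, 77 of 410 pseudogenes were higher and 12 lower, and 20 of 71 ncRNA genes were higher and 1 lower. The share of reads on ncRNA genes was 0.163% and 0.188% in the OP50 libraries and 0.320% and 0.360% in the MI-OMU01 libraries.

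**Figure D3:**
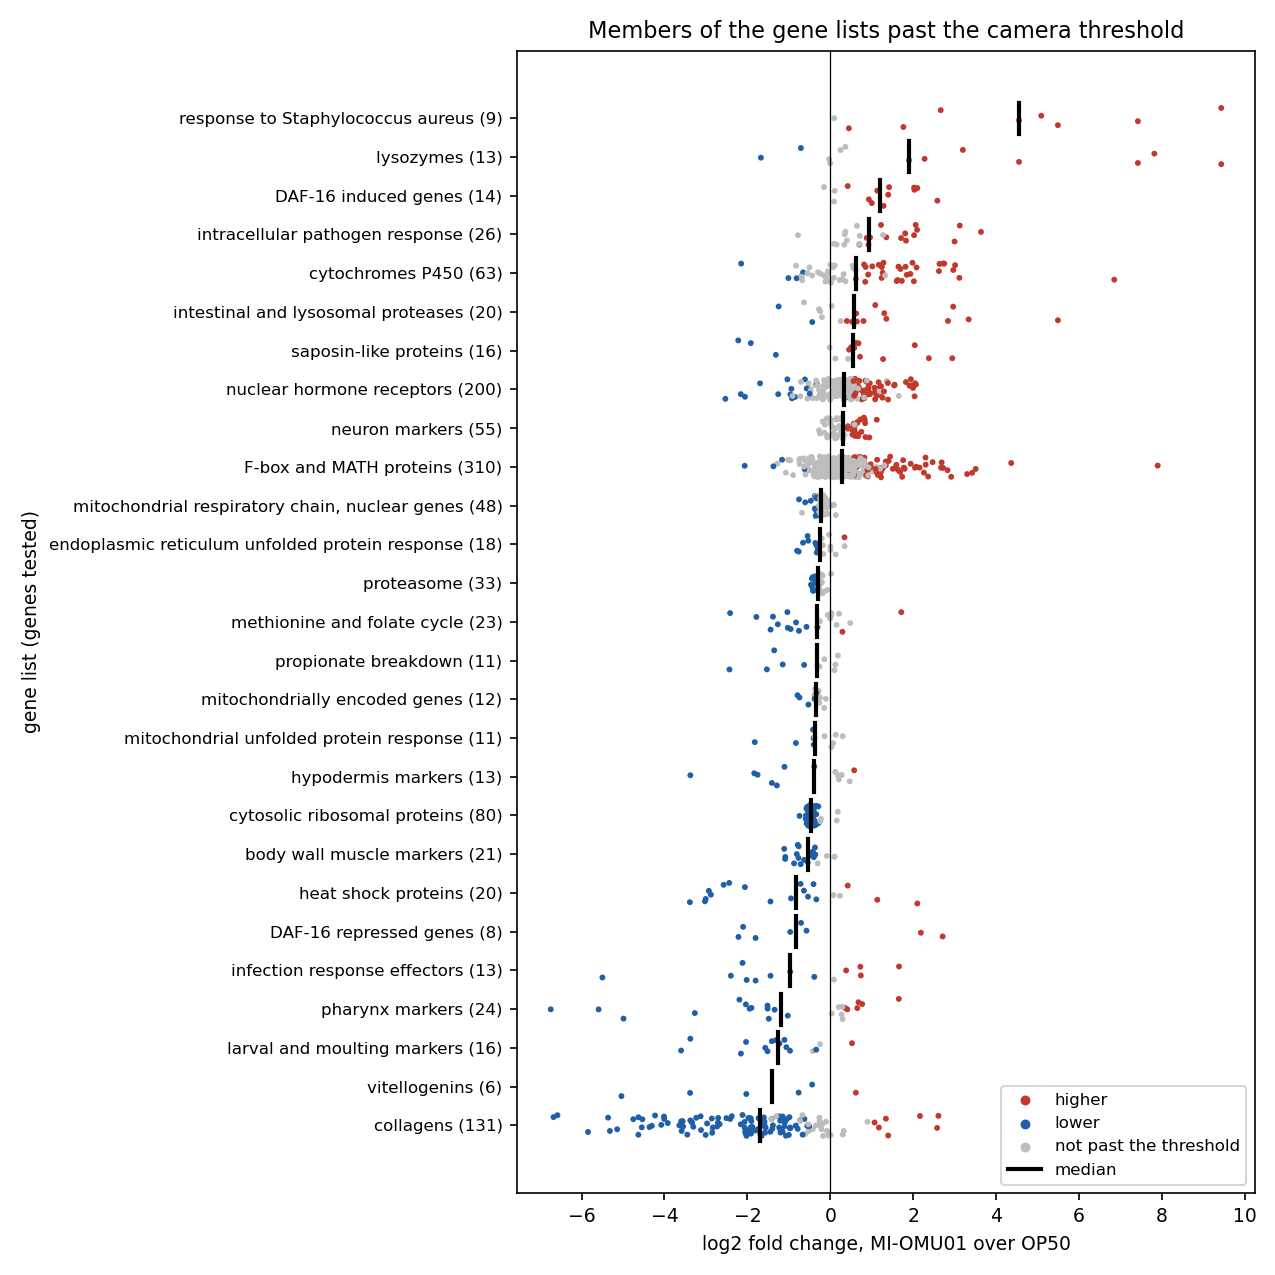
Log2 fold change (MI-OMU01 over OP50) of each tested member of the 27 lists past the camera threshold, 1 point per gene, red for higher, blue for lower and grey for genes not past the threshold, with black bars for list medians and the number of tested genes after each name. Medians run from 4.55 for the genes responding to S. aureus to -1.68 for the collagens, and none of these medians changed sign with another scaling.

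Of the 46 lists 27 passed the camera threshold, 10 up and 17 down, with a preset correlation between genes of 0.01. With a correlation estimated from these 4 libraries 0 of the 46 lists passed camera, the smallest adjusted p being 0.261. Camera then uses the few residual degrees of freedom of 4 libraries. The S. aureus list had an estimated correlation of -0.044, below the preset 0.01, and still went from a camera adjusted p of 1.82e-35 to 0.261. The loss of all calls therefore cannot be put down to correlation between genes alone. By the directional fry test, which does not compare a list with other genes, 25 lists passed.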

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

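The alternatives with thinned libraries and with summed copies were added after the genes of the comparison had been seen, and the other alternatives were chosen before. No gene called in the comparison changed sign under the alternatives in which it was tested, and of the 4449 calls 3495 were shared with DESeq2, 4402 with limma-voom, 4320 with DESeq2 size factors and 3884 with total counts as library sizes. With glmTreat against a fold of 1.5, 1668 genes passed (771 higher, 897 lower) and 137 of the named genes, which follows from the larger fold asked for. The filter at 5 CPM left 468 genes higher and 615 lower by at least 2-fold, with fewer genes tested (10393). When 1 library was left out, 2935 to 4571 genes passed, 1262 to 2297 higher and 1505 to 2563 lower, with the lone library of a group assumed to vary like the other group. The lowest total came without MI-OMU01 replicate 2, and the lowest count of lower genes without MI-OMU01 replicate 1. The cause was not tested beyond the smaller number of samples. Left-out libraries gave 25 to 28 lists past the camera threshold and 175 to 200 named genes.

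Camera with an estimated correlation passed 0 lists and the mixed fry test, which counts change in either direction, 42. Results that were not past the threshold changed sign. For skn-1 the log2 fold change was 0.12 with total counts, 0.0216 with the stricter filter, 0.0645 without the length trend, and -0.15 to 0.0900 when 1 library was left out. The camera direction turned for oocyte and germline markers with total counts (adjusted p = 0.767), the stricter filter (0.794), the length trend removed (0.873), protein-coding genes only (0.979), without OP50 replicate 1 (0.123) and without MI-OMU01 replicate 2 (0.474). It turned for the antioxidant and SKN-1 target genes with total counts (0.964), without MI-OMU01 replicate 1 (0.828) and without replicate 2 (0.971), for the hypoxia response without OP50 replicate 1 (0.982) and without MI-OMU01 replicate 2 (0.944), and for antimicrobial peptides with the length trend removed (0.553). Over all 4 left-out libraries, turned or not, the adjusted p ran from 0.0817 to 0.474 (oocyte and germline), 0.828 to 0.982 (antioxidant) and 0.478 to 0.982 (hypoxia). The cause was not tested. Removal of the length trend ended the camera calls of the endoplasmic reticulum (0.0974) and mitochondrial (0.0527) unfolded protein responses, and use of protein-coding genes only that of the former (0.0559). The stricter filter ended the camera calls of both responses (0.124 and 0.0684), of the nuclear respiratory chain genes (0.0866) and of mitochondrially encoded genes (0.0510). Directional fry did not pass the proteasome (0.109), nuclear hormone receptor (0.204), muscle (0.0841), pharynx (0.103), neuron (0.208) and mitochondrially encoded (0.0638) lists. Lists gained were insulin-like peptides (0.0318) and glycolysis (0.0175) with limma-voom, fatty acid oxidation (0.0281) and glycolysis (0.0239) with no filter, and glutathione S-transferases (0.0228) with the stricter filter. Of the 92 counts of higher or lower list members, those that moved by over 1.5 times numbered 21 with total counts, 18 with DESeq2 and 19 with the stricter filter. They numbered 15 with the replicate number as a block, 11 with the length trend removed, 9 with no filter, 3 with DESeq2 size factors and 56 with glmTreat. Directional fry gained UDP-glycosyltransferases (0.0398), fatty acid synthesis (0.0160), lipases (0.0468) and haem and iron handling (0.0194).

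The labels state no pairing of same-numbered libraries. Deviations of same-numbered libraries from their group mean correlated at 0.14 across genes. With 2 libraries per group the 2 pairs give the same value, so it does not decide whether they were paired. With the replicate number as a block 5807 genes passed (2890 higher, 2917 lower), and the oocyte and germline list turned to up (adjusted p = 0.966). The block ended the calls of hsp-70 (adjusted p = 0.0821) and hsp-16.2 (0.157), with log2 fold changes of -3.01 (-3.02 without it) and -3.07, since their SE went from 0.188 to 0.409 and from 0.523 to 0.668. It brought lys-7 past the threshold (adjusted p = 0.0115). The correction for GC content was not run. With libraries thinned to 1 total, 14806 genes were tested instead of 14967 and 4402 passed instead of 4449. Recovery of simulated changes was not measured by expression level.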

Other observations

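The gene families of the next paragraph and the tests on col-19, larval timing genes, scaling, somatic and germline markers, plate handling, propionate genes and autophagy genes were chosen after their results were seen, while those on depth, even background and summed copies were set after the genes of the comparison had been seen but before their own results were.

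Families of at least 8 tested genes, grouped by name, were tested with camera over 179 families, of which 35 passed, and 0 with an estimated correlation. Neuropeptide genes were higher, 19 of 30 flp and 38 of 66 nlp genes, with 0 and 3 lower (adjusted p = 0.000266 and 0.000598; adjusted p = 0.995 with an estimated correlation for both). The flp genes are also in the list of neuron markers, so the 2 calls are not separate. Of 15 chil genes, which code for chitinase-like proteins, 10 rose and none fell (adjusted p = 0.000619; 0.819 with an estimated correlation). Hedgehog-related genes fell, with 12 of 13 grd and 7 of 9 wrt genes lower and none higher, and 10 of 17 grl genes lower and 2 higher (adjusted p = 2.44e-13, 9.60e-10 and 3.92e-06; 0.819 with an estimated correlation for each). Of 29 nas genes, which code for astacin metalloproteases, 17 fell and 2 rose (adjusted p = 4.39e-06; 0.995 with an estimated correlation). Genes of the cytosolic chaperonin (8 of 8 cct genes) and of mitochondrial ribosomes (22 of 42 mrpl and 18 of 29 mrps genes) also fell, with none higher (adjusted p = 0.00297, 0.000988 and 0.00471; 0.995, 0.933 and 0.819 with an estimated correlation).

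Collagen and moulting genes were lower together, with some genes in both lists. The scaling of libraries does not account for it, since the collagen median closest to 0 over 3 scalings was -1.55. Larvae or embryos carried in the OP50 libraries could not lower col-19, a collagen gene of the adult stage, which had a log2 fold change of -3.01. For the moulting-cycle genes such larvae may still contribute: the larval timing genes lin-14, lin-28 and hbl-1 had a median log2 fold change of 0.45, but their level in these worms is high enough to hide a small share of larvae. The col-19 value bears on carried larvae or embryos only. Whether the worms themselves were at the same stage in each group was not tested. A difference in cuticle gene transcription between the diets stays open as a hypothesis and was not tested.

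Weakly expressed genes were higher in MI-OMU01-fed worms: among protein-coding genes at 1 to 5 CPM the median log2 fold change was 0.19 and 505 were higher against 328 lower, while above 500 CPM it was -0.34 with 41 higher and 144 lower. The medians of the F-box and MATH (0.28), nuclear hormone receptor (0.34) and neuron (0.31) lists lay near that of genes at up to 1 CPM (0.32). Ribosomal protein genes (-0.46) moved in the direction of abundant genes. In the main test camera compared lists with genes of every level, and the levels of list members were not matched to these bins. These list calls were therefore not told apart from the trend there. The F-box and MATH, nuclear hormone receptor and neuron calls did not end with the filter of 5 CPM in 2 libraries. That filter can keep a gene through its higher group alone, so it does not settle the question. Depth does not account for the rise of weakly expressed genes, since after thinning to 1 total the lower MI-OMU01 library held 771 more genes with a read than the higher OP50 library. A background even per kb, as from genomic DNA, could give at most 12.7% or 28.2% of the rise in genes at up to 1 CPM, depending on where its density was taken. The first value, from genes without a read in OP50 replicate 1, was computed after 2 other versions. These gave 28.2% with the density of all genes at up to 1 CPM, and -5.20% when that of OP50 replicate 2 was subtracted. A lower share of germline RNA alone would raise all somatic markers alike over germline markers. Medians of 5 somatic lists lay up to 1.49 apart (SE 0.440), and muscle markers lay 0.53 below germline markers (SE 0.0811). These SE were computed for differences between list means, not medians. They also take genes as independent. The estimated correlation between genes was 0.67 for muscle and 0.96 for germline markers, so the SE are too small. The lowest list, pharynx markers, also holds the falling abu family. A lower germline share together with separate regulation of muscle or pharynx genes would not be seen by this test and stays open. A rise of neuronal transcripts and an unlabelled difference in library batch or RNA quality stay open, with 5 of 12 mitochondrially encoded genes lower (camera adjusted p = 0.0138; adjusted p = 0.530 with an estimated correlation, 0.0510 with the stricter filter and 0.0638 by directional fry) and histones not past the threshold (0.184).

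Heat shock genes were lower. A split of reads within the copy pairs hsp-16.1 with hsp-16.11 and hsp-16.48 with hsp-16.49 does not account for their fall. Shared reads that were lost in counting would not come back in a sum, so their part was not tested. Summed, these pairs stayed lower in edgeR (log2 fold change -2.97 and -2.48, adjusted p = 4.18e-05 and 2.19e-06). The third summed pair, hsp-16.2 and hsp-16.41 (adjusted p = 0.0294), is not made of near-identical copies, so shared reads were not tested for hsp-16.2. Handling of the OP50 plates cannot be told apart from the diet, because no label records it for either library. The OP50 libraries differed by a median of 0.29 on the log2 scale over hsp-16.2, hsp-16.41, hsp-70 and hsp-110, which could come from handling or from chance. A diet effect on heat shock transcription stays open.

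A hypothesis is that MI-OMU01-fed worms transcribe the propionate shunt less, as is known when vitamin B12 is ample or propionate is low. The 5 shunt genes had a mean log2 fold change of -1.26 and the 6 genes of the vitamin B12-dependent arm -0.19 (one-sided exact permutation over 462 arrangements of genes, p = 0.0152). In the shunt alh-8 did not pass the threshold (log2 fold change 0.18), and in the arm mmaa-1 fell (log2 fold change -0.63). Genes are not independent samples and the split was made with the values known, so this may describe these libraries only, and neither vitamin nor propionate was measured here.

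A general rise of autophagy and lysosome genes could have gone with the rise of lysosomal lipases and lysozymes. That list had a camera adjusted p of 0.569 and a median of -0.01, with 10 higher and 5 lower of 45, which does not exclude a small rise. The intestinal and lysosomal proteases had 12 higher and 2 lower of 20 (camera adjusted p = 8.45e-10, and 0.301 with an estimated correlation). Of 20 lipases 6 were higher and 7 lower, with a median of 0.02. A rise of some lysosomal enzymes without the rest of the list stays open.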
